A study of Saccharomyces cerevisiae with 20 samples.

How the data were processed

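Polyadenylated RNA of 9 yeast genotypes was measured in 20 libraries. Per the labels' protocols, RNA was extracted with acid phenol from cells in mid-logarithmic growth and treated with DNase I, cDNA was primed with d(T)23VN and sonicated to about 250 bp, and libraries were made by tailing and ligation of single strands. The values used here are read counts per annotated feature, in the table of raw counts that the authors deposited. Per the submitters' processing notes, bcl2fastq 2.17, Trim Galore 0.6.7, Bowtie2 2.2.5 and featureCounts 2.0.3 were used with the sacCer3 genome; the strand setting of the counting, the treatment of reads with several positions and the removal of PCR copies are not given in the sources used here.

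The table held 7127 features, of which 6047 were matched by locus tag to the R64 annotation and 6038 of those had the same coordinates. Overlap with another feature was found for 1426 features. Samples were grouped by the genotype in their labels. No feature was removed before testing except by edgeR's filterByExpr, which left 6554 genes.

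All 20 libraries were fitted together in edgeR 4.0.16 with TMM scaling and the quasi-likelihood F test, with a mean per genotype, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The SE of a log2 fold change is its absolute value divided by the square root of F. The biological coefficient of variation was 14.6%. Each mutant was compared with BY4741, and the 3 SWI/SNF mutants with each other. Gene lists, 42 in number and fixed before the counts were seen, were tested by camera in limma 3.58.1 with a preset correlation of 0.01, and again with the correlation estimated from the residuals; p-values were adjusted over the 328 combinations of list and mutant, and over the direct comparisons separately. The self-contained test fry was run beside it, and gave an adjusted p of 1.36e-07 for the ribosomal protein list in def1Δ. Members of a list were also adjusted over the list alone.

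Genes were named by a rule fixed beforehand: in each comparison with BY4741 the 8 largest rises and 8 largest falls among genes that passed, had a mean of 20 CPM or more in a group and had no overlap between the libraries of the 2 groups; 3 members of each of the 5 most strongly called lists; 5 rises and 5 falls in each direct comparison; and the deleted and marker genes. The text prints a part of these, and says where a gene was chosen after its values were seen. For a group with 0 counts a floor of 3 counts over the group was used, and for 1 to 3 counts an exact 95% interval of the ratio.

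The test was checked on simulated counts with the depth and dispersion of the libraries and 100 genes changed at each fold. The changed genes had a mean of 20 CPM or more in BY4741, so recovery at lower levels was not checked. Rises and falls were equal in number, and far fewer genes changed than were called in the comparisons of mutants with BY4741. At 2-fold it recovered 95% of changed genes with the depth of the def1Δ comparison, 75% with that of nam7Δ and 87% with that of snf6Δ, and at 4-fold 100%, 99% and 100%, with 9, 10 and 14 false calls among 6367, 6377 and 6365 genes. The effect of sharing the noise of BY4741 on correlations and overlaps was measured in 100 simulations of unchanged mutants. In each, all libraries, those of BY4741 included, were drawn anew from the BY4741 means.

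Alternatives were the size factors of DESeq2, library totals, no filter on low counts, a minimum change of 1 on the log2 scale, the Wald test of DESeq2 1.42.0, a block for replicate number, a fit of the 2 genotypes alone, and leaving out each library. Chosen after seeing the data were nuclear protein-coding genes alone, features that overlap no other, the equal-weight mean of the other mutants outside the SWI/SNF trio in place of BY4741, and def1Δ without chromosome III or without chromosomes II, III, XIV and XV. R 4.3.3, Biostrings 2.70.1, python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Reads were not analysed here, so splicing, sequence variants and copy number were not measured directly.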

Results

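RNA was sequenced from budding yeast of the laboratory strain BY4741 and from 8 deletion mutants, in a study that set up mDRIP-seq, a sequencing assay for mapping R-loops (an RNA:DNA hybrid with a displaced DNA strand). The RNA libraries were made from polyadenylated RNA of cells in mid-logarithmic growth. The mutants lacked DEF1 (degradation of stalled RNA polymerase II), DHH1 (a DEAD-box helicase that activates mRNA decapping), MED1 (a Mediator subunit), NAM7 (the Upf1 helicase of nonsense-mediated decay) or RAD51 (the strand-exchange protein of homologous recombination). The remaining 3 lacked SNF2, SNF5 or SNF6, subunits of the SWI/SNF chromatin remodelling complex, of which Snf2 is the ATPase. There were 20 libraries, 3 each of BY4741 and def1Δ and 2 of each other mutant. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

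The libraries held 1004601 to 4748365 counts each. The totals, in replicate order, were 3406984, 1913732 and 1705684 counts for BY4741 and 1980421, 3640121 and 4748365 for def1Δ. They were 2718287 and 3746524 for dhh1Δ, 2658262 and 4249209 for med1Δ, 1487222 and 1195103 for nam7Δ, and 1710805 and 2359914 for rad51Δ. The SWI/SNF mutants had 2494855 and 2173281 (snf2Δ), 3050147 and 3415345 (snf5Δ), and 4108084 and 1004601 (snf6Δ). A total of 3 counts, the most that a count of 0 allows, corresponded to 0.63 to 2.99 CPM across libraries. Features of the ribosomal DNA locus took 16.78% to 48.91% of the counts, with 45.4% ± 4.97 (SD, n = 2) in nam7Δ and 30.2% ± 8.91 (n = 3) in BY4741. Cytosolic ribosomal protein genes took 3.16% ± 0.23 of the nuclear protein-coding counts in BY4741 and more in every mutant library, from 5.13% ± 1.77 in nam7Δ and 7.93% ± 1.20 in rad51Δ to 17.8% ± 0.438 in snf5Δ. Mitochondrially encoded features took 0.034% ± 0.015 of the counts in snf2Δ and 0.554% ± 0.179 or more in every other genotype, with 0.856% ± 0.175 in BY4741.

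**Figure D1:**
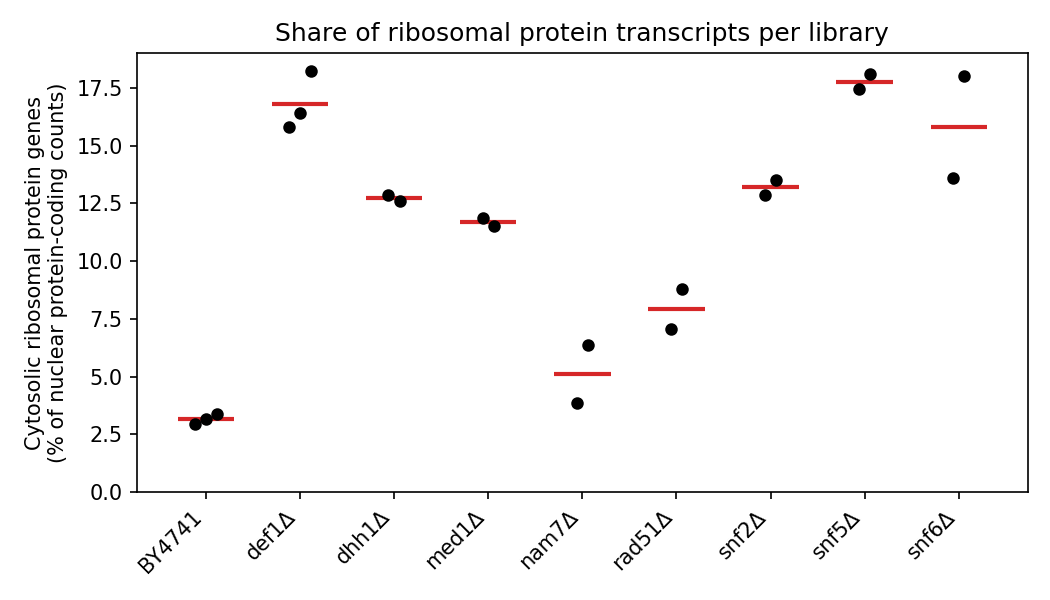
The vertical axis gives the counts of cytosolic ribosomal protein genes as a percent of all nuclear protein-coding counts, for the genotypes on the horizontal axis. Points are libraries and red lines are group means. The 3 BY4741 libraries lie below every library of the 8 mutants.

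Each deleted gene was examined in every library before any comparison. DEF1 had 5, 9 and 12 counts in the def1Δ libraries and 73 or more in every other library. DHH1 had 25 and 23 counts in dhh1Δ and at least 118 elsewhere, and MED1 had 4 and 4 counts in med1Δ and at least 25 elsewhere. NAM7 had 22 and 15 counts in nam7Δ and at least 106 elsewhere. RAD51 had 1 and 0 counts in rad51Δ and at least 17 elsewhere. SNF2 had 33 and 24 counts in snf2Δ and at least 116 elsewhere, SNF5 had 17 and 14 in snf5Δ and at least 41 elsewhere, and SNF6 had 10 and 6 in snf6Δ and at least 75 elsewhere. On the log2 scale, relative to BY4741, the deleted gene fell by 5.01 ± 0.26 (SE) for DEF1, 3.75 ± 0.22 for DHH1, 4.30 ± 0.36 for MED1 and 1.96 ± 0.24 for NAM7. It fell by 3.35 ± 0.19 for SNF2, 2.96 ± 0.25 for SNF5 and 4.13 ± 0.31 for SNF6. RAD51 was 240-fold lower in rad51Δ, with a 95% counting interval of 42.8 to 9500. Such intervals, and the floors used for counts of 0, cover counting error only, because reads copied by PCR are not independent molecules. The genotype of BY4741 lists 4 marker mutations. LEU2, URA3 and MET17 (also called MET15) had 0 counts in all 20 libraries, and HIS3 had 57 to 556 counts.

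**Figure D2:**
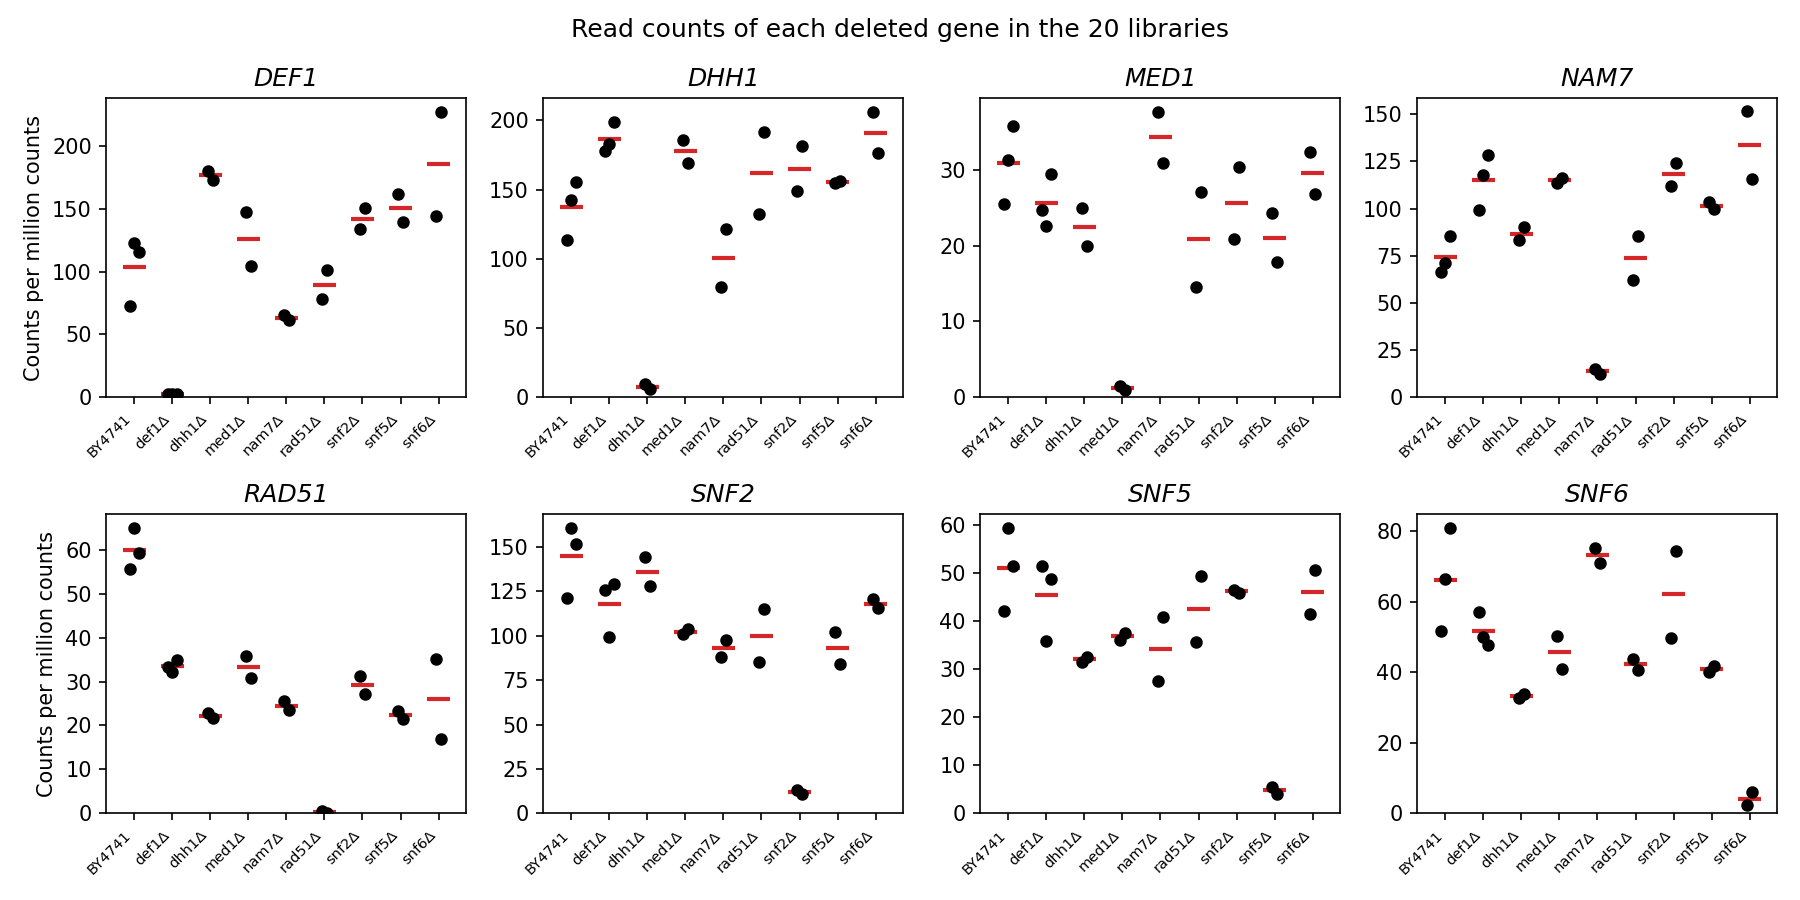
Each panel gives the level of a deleted gene in CPM of the library total, before TMM scaling, for the genotypes on the horizontal axis. Points are libraries and red lines are group means. Each gene is lowest in the 2 or 3 libraries of its own mutant.

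Gene levels below are TMM-normalised CPM (mean ± SD) and changes are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in 6554 genes tested. TMM scaling centres each comparison near no change. With library totals alone the median over all genes lay at -0.22 (snf2Δ) to -0.53 (snf5Δ) against BY4741 and at -0.10 to 0.02 with TMM, so that directions are relative to the bulk of genes. The counting did not state a strand setting, and antisense reading frames nested in genes had a median read density 1.286 times that of the host gene. Genes that overlap another feature, such as HIS3, RNR2, SER3, AI3 and AI5_BETA among those named, are therefore uncertain, as are members of families with near-identical copies (PHO11 and PHO12, SNZ2 and SNZ3, HXT6, the PAU and COS families). The list of mitochondrially encoded genes holds COX1 and COB with reading frames encoded in their introns, which can share reads. Its member counts and p-values are therefore not those of separate genes. For 41 gene lists with 4 or more tested members, limma's camera set each list against all other genes. It called 119 of the 328 combinations of list and mutant, of which 4 held with an estimated correlation between genes: the phosphate list in def1Δ, the seripauperins in nam7Δ, and the daughter-cell and G2/M lists in rad51Δ. The alpha-cell markers, a check for cells of the other mating type, had too few tested members, and MF(ALPHA)1, an alpha-factor gene, had 0 to 5 counts per library.

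**Figure D3:**
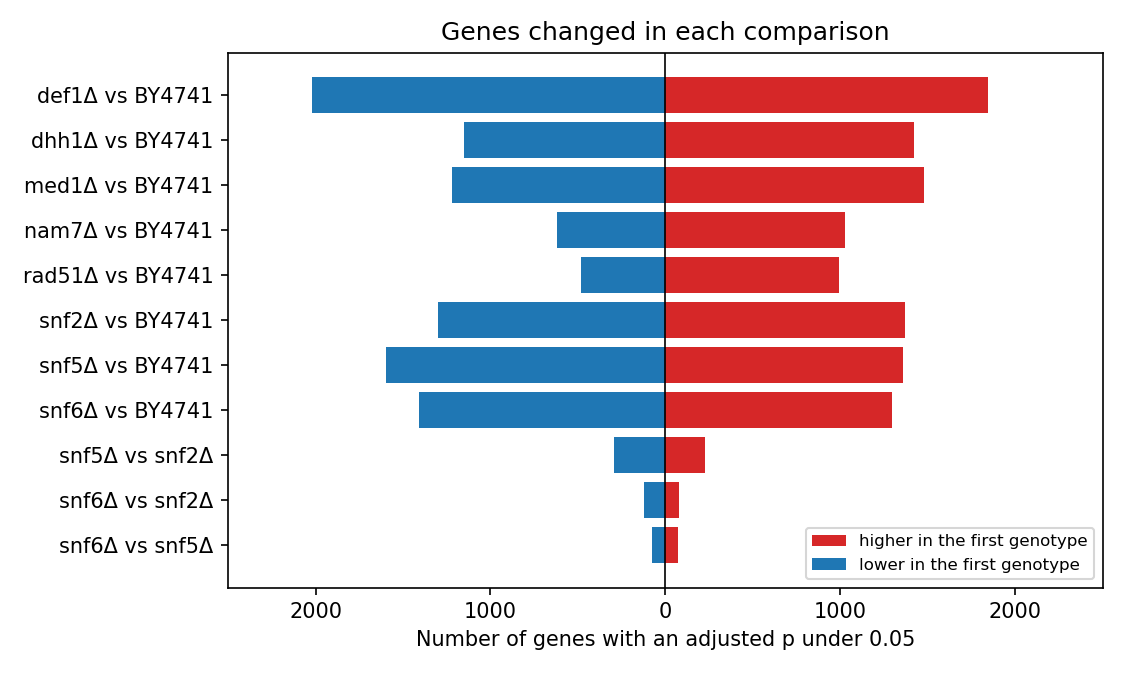
Bars give the number of genes with an adjusted p under 0.05 in each comparison, to the right for genes higher and to the left for genes lower in the genotype named first. def1Δ has the longest bars against BY4741, with 1845 genes higher and 2023 lower, and snf6Δ against snf5Δ the shortest, with 75 and 78.

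The def1Δ comparison asked which transcripts differ when the factor for removal of stalled RNA polymerase II is missing (n = 3 and 3). The largest rises were in the phosphate regulon. PHO84, the high-affinity phosphate transporter (YML123C, chromosome XIII, 24037 to 25800), rose 124-fold, from 18.3 ± 2.77 CPM in BY4741 to 2290 ± 302 in def1Δ (log2 6.95 ± 0.28, adjusted p = 9.46e-16). The acid phosphatase genes PHO11 (YAR071W, chromosome I, 225460 to 226863) and PHO12 (YHR215W, chromosome VIII, 552099 to 553502) rose by 6.64 ± 0.38 and 5.99 ± 0.24, and the sodium-phosphate cotransporter gene PHO89 by 5.23 ± 0.44. The largest falls included HSP26, a small heat shock protein (YBR072W, chromosome II, 382030 to 382674), which fell from 953 ± 12.3 to 17.4 ± 9.41 CPM, and YGP1, a stress-induced secreted glycoprotein, which fell by 5.23 ± 0.35. Of 21 phosphate regulon genes 15 rose, 1 fell and 5 did not pass, with the same 15 and 1 adjusted over the list alone. Their median change was 2.06, or 2.00 with GIT1, which had 0 counts in BY4741, set at its bound, and the list was called at adjusted p = 1e-06 and adjusted p = 0.0405 with an estimated correlation.

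Growth-related lists were higher in def1Δ. Of 138 cytosolic ribosomal protein genes 137 rose, also adjusted over the list alone, among them RPS14B (30.4-fold), RPS28B (16.5-fold) and RPL8A (13.9-fold); the list had adjusted p = 4.91e-57 and adjusted p = 0.171 with an estimated correlation. These genes took 16.8% ± 1.27 of the protein-coding counts in def1Δ. Their median change was 2.93 against BY4741 and 1.03 against the mean of the other mutants outside the SWI/SNF trio. Of 64 ribosome biogenesis genes 63 rose and 1 fell, adjusted over the list alone too, with UTP20, a component of the small-subunit processome, up by 3.01 ± 0.19 (list adjusted p = 4.55e-23 and adjusted p = 0.3 with an estimated correlation). Of 17 genes of purine and one-carbon synthesis 15 rose and 1 fell, by either adjustment including that adjusted over the list alone, led by ADE17 (IMP synthesis, 28.1-fold) and HPT1 (hypoxanthine-guanine salvage, 24.6-fold), with adjusted p = 0.18 with an estimated correlation. All 15 daughter-cell genes rose, also adjusted over the list alone, including PIR1 by 3.11 ± 0.17 and EGT2 by 2.84 ± 0.18, with adjusted p = 0.0913 with an estimated correlation. All 10 histone genes rose, with 10 adjusted over the list alone and a median of 1.59 (adjusted p = 0.169 with an estimated correlation). Of 36 general stress genes 33 fell and 1 rose, 34 and 1 adjusted over the list alone, with TFS1, a carboxypeptidase inhibitor, down by -3.41 ± 0.23 (adjusted p = 0.396 with an estimated correlation). Of 45 genes of the TCA cycle and respiratory chain 29 fell and 1 rose, 30 and 1 adjusted over the list alone (adjusted p = 0.396 with an estimated correlation). The list of RNA polymerase II and elongation factors, chosen for the function of Def1, had 17 members higher, 6 lower and 6 not passing, the same 17 and 6 adjusted over the list alone (adjusted p = 0.0482 and adjusted p = 0.396 with an estimated correlation).

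In total 3868 genes changed in def1Δ, 1845 higher and 2023 lower. Scaled by library totals alone, the split was 1181 higher and 2621 lower. camera called 19 of 41 lists, and the 18 not held with an estimated correlation then had adjusted p = 0.0913 to 0.675. Genes of chromosome III had a median log2 ratio to the other mutants of -0.98, -0.85 and -1.08 in the 3 def1Δ libraries, while chromosome II had 0.36, 0.38 and 0.34, chromosome XIV -0.27, -0.19 and -0.18, and chromosome XV -0.28, -0.25 and -0.26. Every other chromosome lay between -0.06 and 0.2 in every def1Δ library. Without chromosome III 3732 genes changed.

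**Figure D4:**
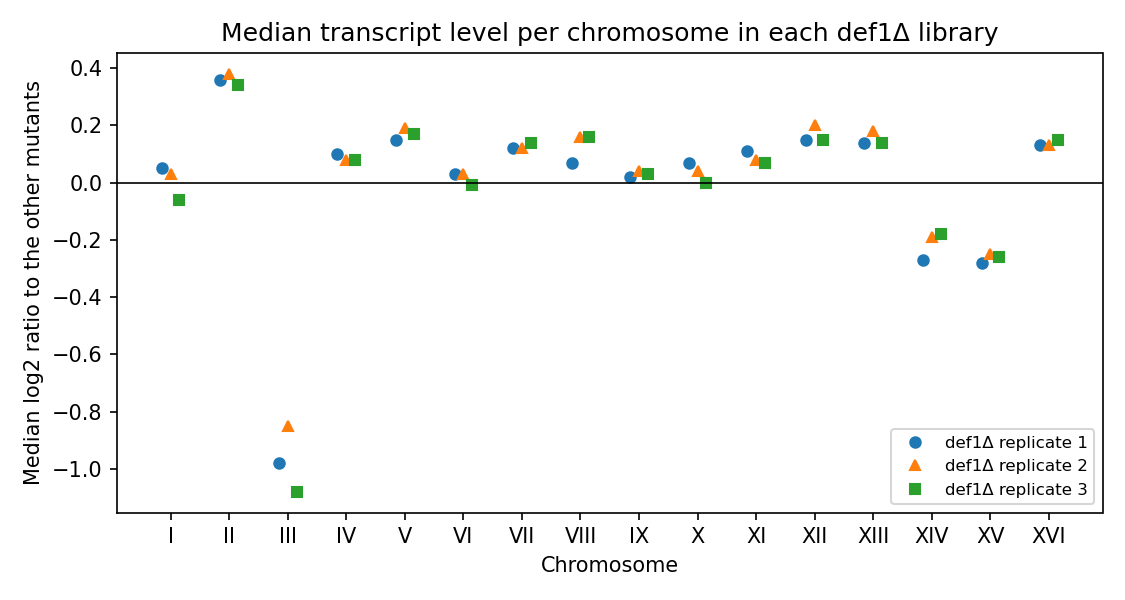
Symbols give the median log2 ratio of the genes of each chromosome (horizontal axis) in each def1Δ library against the mean of the other mutants (vertical axis), with a line at 0. Chromosome III lies at -0.85 to -1.08 in the 3 libraries.

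The dhh1Δ comparison asked which transcripts differ without the decapping activator (n = 2 and 3). SNZ2 (YNL333W, chromosome XIV, 13267 to 14163) and SNZ3, near-identical vitamin B6 synthesis genes, rose 102-fold and 84.8-fold, from 0.975 ± 0.245 to 103 ± 9.7 CPM for SNZ2 (log2 6.67 ± 0.30, adjusted p = 1.65e-14). RDS1, a zinc-cluster regulator gene near the right end of chromosome III (YCR106W, 310958 to 313456), had 0 counts in BY4741 and was at least 44.9-fold higher in dhh1Δ, against a floor of 3 counts over the group. The end of chromosome III was near 0 in BY4741, and RDS1 had 14 or more counts in every mutant library, so the difference was not particular to dhh1Δ. PHO84 rose 45.3-fold and ADE17 19.3-fold. CIT2, peroxisomal citrate synthase (YCR005C, chromosome III, 120946 to 122328), fell from 700 ± 74 to 52 ± 12.8 CPM (log2 -3.75 ± 0.20), and NCE103, carbonic anhydrase, fell by 2.76 ± 0.23. Mitochondrially encoded genes were higher: of 17 tested 15 rose, 17 adjusted over the list alone, with OLI1, a subunit of ATP synthase, up by 3.96 ± 0.34 (list median 2.48, adjusted p = 2.3e-08 and adjusted p = 0.327 with an estimated correlation). This list, kept as a sign of RNA quality, was also called higher in def1Δ (median 1.40), med1Δ (1.64), nam7Δ (1.40), rad51Δ (1.74) and snf5Δ (0.81). None of these calls held, with adjusted p = 0.469, 0.427, 0.449, 0.329 and 0.577 with an estimated correlation in that order. As a share of all counts, mitochondrial features took 0.885% ± 0.249 in def1Δ, 0.871% ± 0.009 in med1Δ and 0.68% ± 0.091 in snf5Δ. They took 1.165% ± 0.075 in nam7Δ and 1.112% ± 0.25 in rad51Δ, against 0.856% ± 0.175 in BY4741. The share and the list median thus differ in def1Δ and med1Δ, and in snf5Δ they go in opposite directions.

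Nuclear genes of respiration and fermentation were higher in dhh1Δ as well. Of 45 TCA cycle and respiratory chain genes 30 rose and 3 fell, 32 and 3 adjusted over the list alone, including ATP2, a subunit of ATP synthase, by 1.72 ± 0.17 (adjusted p = 0.328 with an estimated correlation). Of 24 glycolysis and fermentation genes 20 rose, 21 adjusted over the list alone, and none fell (adjusted p = 0.31 with an estimated correlation). Ribosomal protein genes rose in 136 of 138 cases, also adjusted over the list alone, with RPL8A up by 4.21 ± 0.18 (adjusted p = 0.133 with an estimated correlation), and took 12.7% ± 0.17 of the protein-coding counts. Their median change was 2.56 against BY4741 and 0.54 against the mean of the other mutants outside the SWI/SNF trio. Ribosome biogenesis genes rose in 54 of 64 cases, with 57 higher and 1 lower adjusted over the list alone, among them RRP5 by 2.06 ± 0.18 (adjusted p = 0.368 with an estimated correlation). Of 15 daughter-cell genes 12 rose, 13 adjusted over the list alone, with SCW11, a cell wall glucanase, up by 2.49 ± 0.16 (adjusted p = 0.0541 with an estimated correlation). The iron regulon fell in 15 of 27 genes, 17 adjusted over the list alone, with a median of -0.92 (adjusted p = 0.22 with an estimated correlation). Proteasome genes fell in 12 of 35 cases and rose in 1, the same adjusted over the list alone (adjusted p = 0.365 with an estimated correlation). Among 29 factors of mRNA decapping and decay, the list of Dhh1 itself, 6 rose, 4 fell and 19 did not pass, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.966).

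In dhh1Δ 2574 genes changed, 1422 higher and 1152 lower, and by library totals alone 678 were higher and 2265 lower. camera called 16 lists, of which none held with an estimated correlation (adjusted p = 0.0541 to 0.577).

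The med1Δ comparison asked which transcripts differ without a subunit of the Mediator complex (n = 2 and 3). The largest rises again held phosphate genes: PHO84 rose 34.7-fold, PHO3, a constitutive acid phosphatase gene (YBR092C, chromosome II, 427698 to 429101), rose from 24.1 ± 3.98 to 672 ± 61.2 CPM (log2 4.79 ± 0.38, adjusted p = 1.58e-10), and its neighbour PHO5 rose by 4.16 ± 0.26. HXT6, a high-affinity hexose transporter gene, rose from 64.2 ± 16.1 to 1090 ± 185 CPM, and YHB1, flavohaemoglobin, by 4.17 ± 0.25. CIT2 fell by 3.35 ± 0.20 and SHC1, a chitin synthase activator, by 3.50 ± 0.35. Genes of a-cells and the pheromone response were higher: 17 of 26 rose and 2 fell, 18 and 2 adjusted over the list alone, at adjusted p = 8.56e-06 and adjusted p = 0.092 with an estimated correlation. In this list AGA1, an agglutinin subunit, rose by 2.51 ± 0.17 and STE2, the alpha-factor receptor, by 1.53 ± 0.15, both chosen after their values were seen.

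Of 21 phosphate genes 13 rose and 2 fell in med1Δ, the same 13 and 2 adjusted over the list alone (adjusted p = 0.0541 with an estimated correlation). Ribosomal protein genes rose in 135 of 138 cases, also adjusted over the list alone, with RPL15A up by 3.45 ± 0.19 (adjusted p = 0.143 with an estimated correlation), and took 11.7% ± 0.219 of the protein-coding counts. Their median change was 2.48 against BY4741 and 0.46 against the mean of the other mutants outside the SWI/SNF trio. Ribosome biogenesis genes rose in 57 of 64 cases and fell in 1, 59 and 1 adjusted over the list alone, including RPA135, a subunit of RNA polymerase I, by 2.27 ± 0.23 (adjusted p = 0.352 with an estimated correlation). Purine and one-carbon genes rose in 14 of 17 cases and fell in 1, 14 and 2 adjusted over the list alone, with ADE12 up by 2.07 ± 0.16 (adjusted p = 0.22 with an estimated correlation). Of 47 other genes of amino acid synthesis 28 rose and 3 fell, 28 and 3 adjusted over the list alone, among them ARO4, of the aromatic pathway, by 2.56 ± 0.19 (adjusted p = 0.396 with an estimated correlation). Of 15 daughter-cell genes 11 rose, 11 adjusted over the list alone, with PST1, a cell wall protein, up by 1.92 ± 0.16 (adjusted p = 0.133 with an estimated correlation). Proteasome genes fell in 19 of 35 cases and rose in 2, 24 and 2 adjusted over the list alone (adjusted p = 0.297 with an estimated correlation). The iron list had 12 higher and 2 lower of 27, also adjusted over the list alone, at a median of 0.33 with TMM and -0.03 with library totals alone (adjusted p = 0.422 with an estimated correlation). Of 25 Mediator subunit genes 7 fell, MED1 among them, and 1 rose, 6 and 1 adjusted over the list alone, and camera did not call the list (adjusted p = 0.0916).

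In med1Δ 2704 genes changed, 1482 higher and 1222 lower, and by library totals alone 850 were higher and 2093 lower. Against the mean of the other mutants outside the SWI/SNF trio in place of BY4741, a reference chosen after seeing the data, 1470 changed and the daughter-cell list, at a median of 0.005, was not called. camera called 17 lists against BY4741, of which none held with an estimated correlation (adjusted p = 0.0541 to 0.629).

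The nam7Δ comparison asked which transcripts differ without the central helicase of nonsense-mediated decay (n = 2 and 3). The largest rises lay near chromosome ends. On the right end of chromosome III, RDS1 had 0 counts in BY4741 and 92 in nam7Δ, at least 80.3-fold higher, and GIT1, a glycerophosphoinositol transporter gene (YCR098C, 297049 to 298605), was at least 48.0-fold higher. ADH7, an alcohol dehydrogenase gene on the same end, was 118-fold higher with a 95% counting interval of 31.7 to 988. This end was near 0 in BY4741, and over all mutant libraries RDS1 had 854 counts, with 14 or more in each, GIT1 204, with 1 or more in each, and ADH7 282, with 0 in the lowest library. The nam7Δ libraries held 92, 55 and 90 of these counts, or 34.3, 20.5 and 33.6 CPM. GEX2, a glutathione exchanger gene near the end of chromosome XI (YKR106W, 661442 to 663289), was 314-fold higher with an interval of 55.4 to 12500. All 10 tested seripauperin genes, a family of subtelomeric cell wall mannoproteins, rose, also adjusted over the list alone, with a median of 2.49 (adjusted p = 7.98e-07 and adjusted p = 0.0429 with an estimated correlation). Among them PAU3 lies on the right end of chromosome III that was near 0 in BY4741, with 1 count there and 55 in nam7Δ. The list was not tested without PAU3. Sulfate assimilation genes rose too: MET3, ATP sulfurylase (YJR010W, chromosome X, 456239 to 457774), from 43.7 ± 2.41 to 482 ± 189 CPM (log2 3.47 ± 0.19, adjusted p = 4.83e-12), and MET14, the next enzyme of the pathway, by 2.49 ± 0.17.

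Of 31 genes of sulfur and methionine metabolism 23 rose and 1 fell in nam7Δ, 24 and 2 adjusted over the list alone (adjusted p = 1.39e-15 and adjusted p = 0.142 with an estimated correlation). Among the largest falls were those of AGP1, an amino acid permease (YCL025C, chromosome III, 76018 to 77919), from 333 ± 43.1 to 42 ± 14.1 CPM, CAR1, arginase, by -2.58 ± 0.27, CPA2 of arginine synthesis by -2.21 ± 0.20 and ASN1, asparagine synthetase, by -2.09 ± 0.20. Of 24 G1/S genes 13 fell, 16 adjusted over the list alone, and none rose, with RNR1, a subunit of ribonucleotide reductase, down by -1.62 ± 0.23 (adjusted p = 0.133 with an estimated correlation). Of 45 TCA cycle and respiratory chain genes 19 fell, 22 adjusted over the list alone, and none rose (adjusted p = 0.327 with an estimated correlation). Histone genes fell in 6 of 10 cases, 7 adjusted over the list alone (adjusted p = 0.256 with an estimated correlation). Ribosomal protein genes rose in 93 of 138 cases, 105 adjusted over the list alone, with a median of 0.84 (adjusted p = 0.415 with an estimated correlation); against the mean of the other mutants the median was -1.59, and they took 5.13% ± 1.77 of the protein-coding counts. Meiosis and sporulation genes rose in 12 of 26 cases, 15 adjusted over the list alone (adjusted p = 0.133 with an estimated correlation), and COS subtelomeric genes in 6 of 12, 7 adjusted over the list alone (adjusted p = 0.329 with an estimated correlation). Galactose genes rose in 5 of 10 cases, 6 adjusted over the list alone (adjusted p = 0.323 with an estimated correlation). Genes of the oxidative stress list rose in 6 of 19 cases and fell in 1, 7 and 1 adjusted over the list alone, at a median of 0.40 with TMM and -0.09 with library totals alone (adjusted p = 0.171 with an estimated correlation).

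Of 16 factors and known substrates of nonsense-mediated decay 7 rose, 1 (NAM7) fell and 8 did not pass in nam7Δ, with 7 and 1 adjusted over the list alone, and camera did not call the list (adjusted p = 0.0764). EST2, the catalytic subunit of telomerase, rose from 10.2 ± 1.4 to 37.9 ± 10.3 CPM (log2 1.86 ± 0.31), chosen after its values were seen. Of 18 telomere and silencing factors 5 rose and 1 fell, 5 and 2 adjusted over the list alone, with no call for the list (adjusted p = 0.691). In nam7Δ 1651 genes changed, 1029 higher and 622 lower. By library totals alone 2540 changed, 468 higher and 2072 lower, and against the mean of the other mutants 3231 changed. Without nam7Δ replicate 2, 1089 changed. Ribosomal DNA features took 45.4% ± 4.97 of the counts in these libraries. camera called 15 lists, of which 14 did not hold with an estimated correlation (adjusted p = 0.133 to 0.744).

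The rad51Δ comparison asked which transcripts differ without the recombination protein Rad51 (n = 2 and 3). HUG1, a small inhibitor of ribonucleotide reductase induced by DNA damage (YML058W-A, chromosome XIII, 158760 to 158966), rose from 6.56 ± 1.51 to 98 ± 11.4 CPM (log2 3.88 ± 0.28, adjusted p = 3.13e-10). Ribonucleotide reductase genes, chosen after their values were seen, rose with it: RNR3 by 3.00 ± 0.30, RNR2 by 1.69 ± 0.17 and RNR4 by 1.19 ± 0.15. The whole list of 30 DNA damage response genes had 9 higher and 4 lower, 11 and 6 adjusted over the list alone, and camera did not call it (adjusted p = 0.233). Of 20 G2/M genes 15 rose, 17 adjusted over the list alone, and none fell, including CLB1, a mitotic cyclin (YGR108W, chromosome VII, 703636 to 705051), by 2.48 ± 0.24 and SWI5, a transcription factor of the exit from mitosis, by 2.33 ± 0.23 (list median 0.94, adjusted p = 3.29e-08 and adjusted p = 0.0429 with an estimated correlation). For the median log2 fold change of G2/M genes, rad51Δ vs BY4741, the value with the other mutants as reference was 0.41. The list was also called higher in def1Δ (0.97), dhh1Δ (0.69), med1Δ (0.85) and snf6Δ (0.59), with adjusted p = 0.133, 0.169, 0.133 and 0.193 with an estimated correlation. Of 15 daughter-cell genes 12 rose, 14 adjusted over the list alone, with EGT2 up by 1.91 ± 0.19 (adjusted p = 6.78e-12 and adjusted p = 0.0435 with an estimated correlation); against the mean of the other mutants their median was -0.01.

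Cell wall genes rose in 16 of 32 cases and fell in 1, 17 and 4 adjusted over the list alone (adjusted p = 0.3 with an estimated correlation), and PIR3, a cell wall glycoprotein gene, rose from 35.4 ± 8.98 to 429 ± 24.2 CPM. Ribosomal protein genes rose in 133 of 138 cases, also adjusted over the list alone, with RPL8A up by 3.01 ± 0.18 (adjusted p = 0.133 with an estimated correlation); against the mean of the other mutants their median was -0.39, and they took 7.93% ± 1.20 of the protein-coding counts. Of 24 glycolysis and fermentation genes 16 rose, 18 adjusted over the list alone, including PDC1, pyruvate decarboxylase, by 1.81 ± 0.24 (adjusted p = 0.297 with an estimated correlation); against the other mutants the list, at a median of 0.176, was not called. General stress genes rose in 20 of 36 cases and fell in 1, 20 and 2 adjusted over the list alone (adjusted p = 0.569 with an estimated correlation). Purine and one-carbon genes rose in 13 of 17 cases, 13 adjusted over the list alone, with ADE17 up by 3.01 ± 0.32 (adjusted p = 0.22 with an estimated correlation); their median against the other mutants was -0.43. Proteasome genes fell in 8 of 35 cases and rose in 1, the same adjusted over the list alone (adjusted p = 0.297 with an estimated correlation). Medians of the ribosome biogenesis, heat shock, phospholipid and mating lists were 0.39, 0.22, 0.18 and 0.34 with TMM, called at adjusted p = 0.000302 to 0.0409, and 0, -0.20, -0.21 and -0.02 with library totals alone. With an estimated correlation these 4 lists had adjusted p = 0.328 to 0.677.

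In rad51Δ 1476 genes changed, 995 higher and 481 lower. By library totals alone 481 were higher and 1447 lower. Without rad51Δ replicate 2, 823 changed, and CTF8 (sister chromatid cohesion) and CSS2, which fell by 1.80 ± 0.45 and 1.73 ± 0.37 in the full set, no longer passed. camera called 14 lists, of which 12 did not hold with an estimated correlation (adjusted p = 0.133 to 0.677).

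The 3 SWI/SNF comparisons asked which transcripts differ without the ATPase or either of 2 further subunits of the remodelling complex (n = 2 and 3 each). In all 3 mutants general stress genes were lower and ribosomal protein genes higher than in BY4741. HSP26 fell by 3.36 ± 0.32 in snf2Δ, 6.10 ± 0.39 in snf5Δ and 5.39 ± 0.38 in snf6Δ, from 953 ± 12.3 CPM to 92.9 ± 8.6, 13.9 ± 2.55 and 23.8 ± 4.69 (adjusted p = 4.25e-09, 3.42e-12 and 3.34e-11). RPL8A, of the large ribosomal subunit (YHL033C, chromosome VIII, 35255 to 36025), rose 12.1-fold, 15.9-fold and 15.2-fold, and RPS13 14.5-fold, 20.6-fold and 17.4-fold. CIT1, mitochondrial citrate synthase (YNR001C, chromosome XIV, 629622 to 631061), fell by 1.87 ± 0.18, 2.06 ± 0.18 and 2.19 ± 0.18. HPT1 rose by 3.86 ± 0.24 in snf5Δ and 3.84 ± 0.25 in snf6Δ.

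Of 36 general stress genes 28 fell in snf2Δ, 34 in snf5Δ and 35 in snf6Δ, or 29, 35 and 35 adjusted over the list alone, and none rose (adjusted p = 0.396, 0.329 and 0.31 with an estimated correlation). Further falls in this list were those of NTH1, neutral trehalase, by 2.16 ± 0.22 in snf2Δ and 2.65 ± 0.23 in snf6Δ, and of SPI1, a cell wall protein, by 3.97 ± 0.35 in snf5Δ. Of 138 ribosomal protein genes 134, 137 and 136 rose, or 135, 137 and 136 adjusted over the list alone (adjusted p = 0.143, 0.133 and 0.133 with an estimated correlation). They took 13.2% ± 0.453, 17.8% ± 0.438 and 15.8% ± 3.15 of the protein-coding counts. Their median changes were 2.41, 2.96 and 2.70 against BY4741. Against the mean of the other mutants outside the trio they were 0.27, 0.83 and 0.59. Of 64 ribosome biogenesis genes 48, 58 and 60 rose and 1 fell in each, with 51, 60 and 60 higher adjusted over the list alone (adjusted p = 0.415, 0.31 and 0.328 with an estimated correlation). Of 45 TCA cycle and respiratory chain genes 32, 35 and 30 fell, or 33, 36 and 30 adjusted over the list alone (adjusted p = 0.328, 0.31 and 0.361 with an estimated correlation). Of 17 purine and one-carbon genes 15 rose in each, 15 also adjusted over the list alone (adjusted p = 0.297, 0.143 and 0.133 with an estimated correlation), with SHM2, serine hydroxymethyltransferase, up 17.0-fold in snf6Δ. Daughter-cell genes rose in 10, 9 and 11 of 15 cases and fell in 3, 3 and 1, or rose in 10, 10 and 11 adjusted over the list alone (adjusted p = 0.193, 0.302 and 0.133 with an estimated correlation).

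Other lists were called in some SWI/SNF mutants. In snf2Δ the mitochondrially encoded genes fell in 14 of 17 cases, 16 adjusted over the list alone, with a median of -3.43 (adjusted p = 1.34e-07 and adjusted p = 0.336 with an estimated correlation), and mitochondrial features took 0.034% ± 0.015 of the counts. Nuclear genes of the mitochondrial ribosome rose in 45 of 67 cases in snf2Δ and fell in 2, also adjusted over the list alone (adjusted p = 0.142 with an estimated correlation), and iron regulon genes rose in 19 of 27, 20 adjusted over the list alone (adjusted p = 0.143 with an estimated correlation). HXT1, a low-affinity hexose transporter gene (YHR094C, chromosome VIII, 290913 to 292625), rose by 3.05 ± 0.24 in snf2Δ and 1.46 ± 0.24 in snf5Δ, chosen after its values were seen. In snf6Δ it passed with all libraries, at 0.65 ± 0.25 (adjusted p = 0.0372), but not with library totals alone, with a replicate block or without any 1 of BY4741 replicates 2 and 3 and snf6Δ replicate 1. In snf5Δ, 28 of 47 other amino acid synthesis genes rose and 5 fell, 30 and 5 adjusted over the list alone (adjusted p = 0.336 with an estimated correlation), and 8 of 14 zinc regulon genes rose and 1 fell, also adjusted over the list alone (adjusted p = 0.45 with an estimated correlation). Ergosterol genes rose in 11 of 24 cases and fell in 4 in snf5Δ, also adjusted over the list alone, at a median of 0.29 with TMM and -0.14 with library totals alone (adjusted p = 0.609 with an estimated correlation). RDS1, with 14 or more counts in every mutant library, was at least 58.3-fold higher in snf5Δ than in BY4741, where its end of chromosome III was near 0, so this was not particular to snf5Δ. In snf6Δ, 11 of 21 arginine and lysine genes fell and 1 rose, also adjusted over the list alone (adjusted p = 0.548 with an estimated correlation), and 11 of 26 mating genes fell and 2 rose, also adjusted over the list alone (adjusted p = 0.31 with an estimated correlation). The 12 genes for SWI/SNF subunits had 1 lower member in each mutant, the deleted gene, and 4, 2 and 3 higher, the same adjusted over the list alone. Classical SWI/SNF targets went both ways, with 4, 6 and 2 of 18 higher and 4, 7 and 9 lower, or 4, 6 and 2 and 4, 7 and 10 adjusted over the list alone, and camera called neither list in any mutant against BY4741.

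Changed genes numbered 2675 in snf2Δ (1373 higher, 1302 lower), 2960 in snf5Δ (1362 and 1598) and 2709 in snf6Δ (1298 and 1411). By library totals alone the splits were 873 and 1545, 740 and 2727, and 861 and 1644. Against the mean of the other mutants outside the trio, 1357 changed in snf2Δ and 1451 in snf6Δ, and the ribosome biogenesis list in snf2Δ, at a median of 0.086, was not called. camera called 12, 13 and 13 lists, of which none held with an estimated correlation (adjusted p = 0.133 to 0.609).

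Genes changed together in the SWI/SNF mutants. Across genes, which are not independent replicates, the correlation of log2 fold changes was 0.85 between snf2Δ and snf5Δ, 0.87 between snf2Δ and snf6Δ, and 0.90 between snf5Δ and snf6Δ. Simulated unchanged pairs of mutants that share the BY4741 libraries gave a median of 0.39. Such mutants hold noise alone, so this is not the part of the observed values that comes from sharing. The covariance was 1.06, 1.03 and 1.16 in the same order, against 0.041 in the simulation for each pair. The simulation leaves out a state of the BY4741 libraries that the comparisons share. Higher in all 3 were 894 genes, and lower in all 3 were 913. Simulated unchanged mutants that share BY4741 had 0 and 0 in common, but also a median of 0 changed genes each, so this value leaves the effects out. Independent lists of these sizes, which leave the shared libraries out, would have 56.5 and 68.3 in common. The 3 BY4741 libraries cannot be divided into parts with 2 libraries each, and part of the excess may come from sharing them.

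Direct comparisons of the SWI/SNF mutants, which leave BY4741 out, asked where the 3 deletions differ (n = 2 and 2 each). Mitochondrially encoded genes were higher in snf5Δ and snf6Δ than in snf2Δ. AI3 (Q0060, mitochondrial genome, 13818 to 19996), an intron-encoded reading frame that overlaps COX1, stood at 13.2 ± 5.95 CPM in snf2Δ, 411 ± 37.2 in snf5Δ and 348 ± 99 in snf6Δ. AI5_BETA had 1 count in snf2Δ and was 145-fold higher in snf5Δ, with a 95% counting interval of 25.8 to 5760. Of 17 mitochondrially encoded genes 14 were higher in snf5Δ than in snf2Δ, 16 adjusted over the list alone (median 4.65, adjusted p = 0.0384 with an estimated correlation), and 14 were higher in snf6Δ than in snf2Δ, 14 adjusted over the list alone (median 4.05, adjusted p = 0.0372 with an estimated correlation). Members that share reads gave near-equal values. Between snf5Δ and snf2Δ these were 4.78, 4.83 and 4.87 for COX1, AI4 and AI5_ALPHA, and 4.61, 4.56 and 4.65 for COB, BI2 and BI4.

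Against snf2Δ, siderophore genes of the cell wall were lower in snf5Δ: FIT3 (YOR383C, chromosome XV, 1060441 to 1061055) fell from 586 ± 34.5 to 57.1 ± 8.42 CPM (log2 -3.36 ± 0.26, adjusted p = 1.08e-09) and its neighbour FIT2 by -3.20 ± 0.34. Of 27 iron regulon genes 13 were lower in snf5Δ than in snf2Δ, 17 adjusted over the list alone, and 11 were lower in snf6Δ, 21 adjusted over the list alone (adjusted p = 0.0372 and 0.0211 with an estimated correlation). Mitochondrial ribosomal protein genes were lower in snf5Δ than in snf2Δ in 34 of 67 cases, 50 adjusted over the list alone, and in snf6Δ in 4, 10 adjusted over the list alone (adjusted p = 0.0211 and 0.0372 with an estimated correlation). Other amino acid synthesis genes were higher in snf5Δ than in snf2Δ in 26 of 47 cases, 41 adjusted over the list alone (adjusted p = 0.0414 with an estimated correlation). Purine and one-carbon genes were higher in snf6Δ than in snf2Δ in 10 of 17 cases, 13 adjusted over the list alone, and pyrimidine genes in 4 of 12, 5 adjusted over the list alone (adjusted p = 0.0414 and 0.043 with an estimated correlation). Classical SWI/SNF targets were lower in snf6Δ than in snf2Δ in 5 of 18 cases, 6 adjusted over the list alone, with a median of -0.70 (adjusted p = 0.0372 with an estimated correlation). Among them SER3, of serine synthesis, which overlaps the SRG1 transcript (YER081W, chromosome V, 322686 to 324095), stood at 1110 ± 1 CPM in snf2Δ, 801 ± 24.8 in snf5Δ and 69.8 ± 3.97 in snf6Δ, with 164 ± 10.1 in BY4741. Hexose transporter genes were lower in snf5Δ than in snf2Δ in 3 of 18 cases and higher in 1, 5 and 1 adjusted over the list alone (adjusted p = 0.428 with an estimated correlation).

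Between snf6Δ and snf5Δ, arginine genes were lower in snf6Δ. ARG1, argininosuccinate synthetase (YOL058W, chromosome XV, 219211 to 220473), was 6.42-fold lower in snf6Δ, at 40.2 ± 3.51 against 263 ± 6.93 CPM, and ARG3 6.28-fold lower. Of 21 arginine and lysine genes 9 were lower, 13 adjusted over the list alone with 1 higher (adjusted p = 6.11e-15 and adjusted p = 0.043 with an estimated correlation). Sulfur and methionine genes were lower in 8 of 31 cases, 16 adjusted over the list alone (adjusted p = 0.0736 with an estimated correlation). SED1, a cell wall protein gene, was 4.38-fold higher in snf6Δ. CLB1 and SNZ1 passed with all libraries, at 1.90 ± 0.27 and -2.15 ± 0.53, but not in every fit with a library left out, CLB1 failing without snf6Δ replicate 1 and SNZ1 without any of the 4. HSP12, a stress gene lower in snf6Δ than in snf2Δ by -3.30 ± 0.62, did not pass without snf6Δ replicate 1.

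Fewer genes changed between SWI/SNF mutants than against BY4741: 521 between snf5Δ and snf2Δ (226 higher, 295 lower in snf5Δ), 200 between snf6Δ and snf2Δ (80 and 120) and 153 between snf6Δ and snf5Δ (75 and 78). By library totals alone the splits were 62 and 470 for snf5Δ and snf2Δ and 96 and 29 for snf6Δ and snf5Δ, and DESeq2's Wald test gave 357 and 234 for snf5Δ and snf2Δ. These counts rest on few libraries. Between snf5Δ and snf2Δ, 239 and 147 genes passed without snf2Δ replicates 1 and 2, and 167 and 164 without snf5Δ replicates 1 and 2, while a fit of those 2 genotypes alone gave 1541. Between snf6Δ and snf2Δ, 111 and 91 passed without snf2Δ replicates 1 and 2. Between snf6Δ and snf5Δ, 58 and 65 passed without snf5Δ replicates 1 and 2, and 95 without snf6Δ replicate 2.

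**Figure D5:**
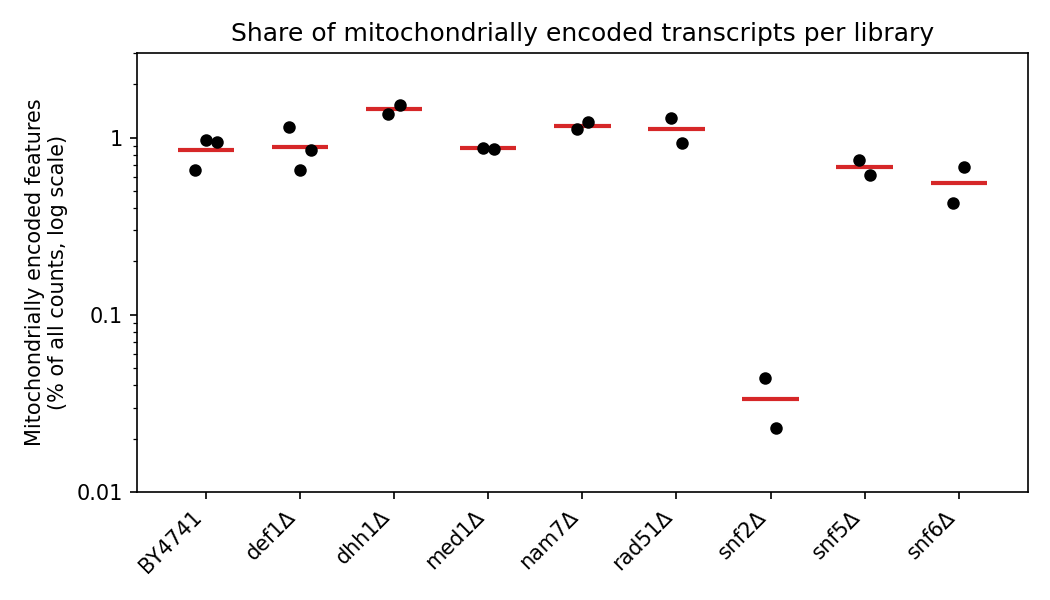
The vertical axis, on a log scale, gives the counts of mitochondrially encoded features as a percent of all counts, for the genotypes on the horizontal axis. Points are libraries and red lines are group means. The 2 snf2Δ libraries lie at 0.044% and 0.023%, below all others.

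Higher in all 8 mutants were 196 genes, of which 92 encode cytosolic ribosomal proteins, and lower in all 8 were 45. These 2 counts were not set against a value for unchanged mutants that share BY4741. The correlation of log2 fold changes across genes, over 28 pairs of mutants, had a median of 0.67, from 0.14 for def1Δ and nam7Δ to 0.90 for snf5Δ and snf6Δ. Simulated pairs of unchanged mutants that share the BY4741 libraries gave means of 0.30 to 0.47. Those mutants hold noise alone, so their values overstate what sharing gives between mutants with effects. For a pair near or below its simulated mean, the correlation alone therefore cannot show whether sharing accounts for it. Every simulated library was drawn from the BY4741 means. A state of the BY4741 libraries that the comparisons share is thus absent from the simulated correlations and covariances. Most pairs with nam7Δ lay near or below their simulated means: 0.14 against 0.35 with def1Δ, 0.23 against 0.32 with dhh1Δ, 0.33 against 0.31 with med1Δ, 0.32 against 0.30 with snf2Δ, 0.34 against 0.31 with snf5Δ and 0.31 against 0.30 with snf6Δ. With rad51Δ it was 0.41 against 0.30. Among genes with a mean of 50 CPM or more, the values were 0.33 with def1Δ and 0.37 with dhh1Δ, moves of over 1.5 times. The covariance had a median of 0.71, against 0.041 in the simulation, and exceeded the simulated value by 0.12 or more in every pair. For pairs with nam7Δ it was 0.16 against 0.04 with def1Δ, and 0.22 to 0.38 against 0.041 to 0.044 with the other mutants. R-loop and RNA:DNA hybrid factors, the list closest to the assay of the study, were not called in any mutant. Of its 34 members 14 rose and 4 fell in def1Δ, 6 and 4 in dhh1Δ, 8 and 4 in med1Δ, 2 and 5 in nam7Δ, and 5 and 2 in rad51Δ. In snf2Δ 8 rose and 4 fell, in snf5Δ 7 and 2, and in snf6Δ 7 and 2. Adjusted over the list alone, the pairs were 14 and 4, 6 and 4, 8 and 3, 2 and 5, 5 and 2, 8 and 3, 4 and 2, and 7 and 2 in the same order (camera adjusted p = 0.0547 in def1Δ and 0.27 to 0.828 elsewhere).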

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

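Of the tests below, those of ribosomal RNA reads, of a state of BY4741, of the dose of chromosome III and of mitochondrial genomes were chosen only after the result was seen; the others were written before. Each result in the next paragraph was picked out because a direct test found a difference between groups, the SWI/SNF mutants.

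Direct tests found 521 genes that differed between snf5Δ and snf2Δ, 200 between snf6Δ and snf2Δ and 153 between snf6Δ and snf5Δ. Some genes moved in opposite directions against BY4741 and also differed directly: 31 for snf5Δ and snf2Δ, 12 for snf6Δ and snf2Δ and 9 for snf6Δ and snf5Δ. The 31 include COX1 and COB, and the 12 include COB, with reading frames in their introns that can share reads. Examples of opposite directions, chosen after these values against BY4741 were seen, are HAP4, BIO2 and SER3. HAP4, the activator of respiratory genes, was 1.15 in snf2Δ and -1.24 in snf5Δ, and BIO2, of biotin synthesis, -1.79 and 1.10. SER3 was 2.77 in snf2Δ and -1.24 in snf6Δ. The median of the mitochondrially encoded genes was 4.65 higher in snf5Δ and 4.05 higher in snf6Δ than in snf2Δ.

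Mitochondrially encoded transcripts were lower in snf2Δ than in snf5Δ and snf6Δ. A lower yield of RNA without long poly(A) tails would lower nuclear small nucleolar and spliceosomal RNAs too, but 67 of them had a median of -0.1. Fewer mitochondrial genomes, or none, would lower nearly all mitochondrial features, and 95.5% of them (21 of 22) lay below -1, with a median of -4.13. This restates the pattern, since 17 of the 22 are the genes that showed it, and some of these overlap. A loss of mitochondrial DNA in the snf2Δ cultures thus stays open. It cannot be told apart from lower transcription or stability of all mitochondrial RNA, and DNA was not measured. Whether such a loss came with the deletion or arose in the cultures sequenced cannot be told from 2 libraries of the same strain.

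Ribosomal protein transcripts were higher in all 8 mutants than in BY4741. Ribosomal RNA reads that take a different part of each library do not account for it in 7 of 7 mutants other than nam7Δ, because the share of ribosomal protein transcripts in nuclear protein-coding counts, which leaves these reads out, lay above that of BY4741 by more than the sum of the 2 SDs; in nam7Δ the gap was 1.97 percentage points against a sum of 2.00, which leaves it open there. For length and expression level, 141 matched genes had medians of 0 to 0.45, below 0.5 of the ribosomal protein median in 8 of 8 mutants. Their median length was 759 bp against 768 bp for ribosomal protein genes, so length does not account for the difference. Their median level over all libraries, the mutants included, was 349 CPM against 526. Expression level was thus matched only in part and is not excluded. A state of the BY4741 libraries, such as a later growth phase, remains open, since 0 of 8 mutants had a library with a share as low as that of BY4741, but alone it predicts mutants that differ less from each other than from BY4741, and nam7Δ had a median 0.84 above BY4741 and 1.59 below the other mutants. An effect common to all mutants predicts the same values, and the 2 cannot be told apart with this design.

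Chromosome III transcripts were lower in def1Δ, with a median of -1.21 over 97 genes. Genes of other chromosomes matched on GC content, length and expression had a median of -0.41 at the lowest of 1000 random sets, so these features do not account for it. A lower dose of the whole chromosome would lower every part of it, and relative to the other mutants, not BY4741, the highest median of any 50 kb window up to position 300000 in any def1Δ library was -0.8, the lowest -1.26; the right end beyond it was not covered. The values are what fewer copies of chromosome III per genome in the def1Δ libraries predict, but copy number was not measured. The windows hold the 97 genes that showed the pattern, so they show only that it runs along the chromosome. A lower dose thus cannot be told apart from lower transcript levels along the whole chromosome. For the smaller shifts of chromosomes II (0.34 to 0.38), XIV (-0.27 to -0.18) and XV (-0.28 to -0.25), no explanation was tested. No biological explanation from the function of Def1 was tested.

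The split of libraries between def1Δ and BY4741 was also examined, over 10 splits of the 6 libraries into 3 and 3. Only 1, the real one, gave as many changed genes (3685 when fitted alone, and 0 at most in any other). Each other split mixes both genotypes in each part, which raises the spread within parts. Few calls were therefore likely there, so 3685 against 0 adds no support. Besides, 10 splits cannot give a share under 0.05.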

How the results depend on the processing

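The alternatives with nuclear protein-coding genes only, with features overlapping no other, with other mutants as reference and without chromosomes were chosen only after the results were seen. For named genes, 4037 of 4151 alternative values kept their direction and their side of the threshold, 54 no longer passed, 15 newly passed and 45 turned direction; for 40 of the called gene lists the numbers were 480 of 524 the same, 40 no longer called and 4 turned. Of 188 alternative summary values 153 stayed within the bounds set for them. All 45 gene values that turned belong to deleted or marker genes near no change, which passed in neither fit. Where a library is left out of a group of 2, the lone sample is assumed to vary like the other groups. In snf6Δ replicate 2 and nam7Δ replicate 2, the libraries with the lowest totals, a count of 3 equals 2.99 and 2.51 CPM, which limits genes of low level. The cause was not tested for any value below unless its setting shows it.

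With a minimum absolute log2 fold change of 1, by construction fewer genes were counted: 2158 in def1Δ, 1256 in dhh1Δ, 1324 in med1Δ, 849 in nam7Δ, 6.9e+02 (rounded to 2 digits) in rad51Δ, 1376 in snf2Δ, 1626 in snf5Δ, 1477 in snf6Δ, 212 between snf5Δ and snf2Δ and 95 between snf6Δ and snf5Δ, with 477 higher and 465 lower in all 3 SWI/SNF mutants. With library totals only 2540 genes changed in nam7Δ. With other mutants as reference the counts were 1470 for med1Δ, 3231 for nam7Δ, 1357 for snf2Δ and 1451 for snf6Δ, and with only the 2 genotypes compared 1541 for snf5Δ and snf2Δ. With an estimated correlation 4 gene lists were called. Among genes with a mean of 50 CPM or more the median correlation between mutants was 0.692, with 0.335 for def1Δ and nam7Δ, 0.954 for snf5Δ and snf6Δ, 0.903 for snf2Δ and snf5Δ and 0.915 for snf2Δ and snf6Δ.

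Leaving out each library gave 1089 to 1448 changed genes in nam7Δ, 823 to 1429 in rad51Δ, 147 to 239 between snf5Δ and snf2Δ, 91 to 173 between snf6Δ and snf2Δ and 58 to 146 between snf6Δ and snf5Δ, by construction with fewer samples. List medians that turned with other mutants as reference were those of ribosomal proteins in nam7Δ (-1.59) and rad51Δ (-0.387), daughter-cell genes in rad51Δ (-0.009) and purine genes in rad51Δ (-0.43). Among all called lists, including those outside these 40, medians turned or reached 0 with library totals only for iron genes in med1Δ (0.33 to -0.03) and nam7Δ (0.35 to -0.14) and oxidative stress in nam7Δ (0.40 to -0.09). In rad51Δ they did so for ribosome biogenesis (0.39 to 0), heat shock (0.22 to -0.20), phospholipid (0.18 to -0.21) and mating genes (0.34 to -0.02), and in snf5Δ for ergosterol genes (0.29 to -0.14). Between snf5Δ and snf2Δ they did so for ergosterol (0.23 to 0) and proteasome genes (0.17 to -0.06). Between snf6Δ and snf5Δ they did so for ribosomal proteins (-0.20 to 0.01), ribosome biogenesis (-0.13 to 0.10) and mating genes (-0.19 to 0.03).

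Gene values that turned with library totals only were MED1, SNF2 and SNF5 in def1Δ (-0.248, -0.289, -0.166), SNF2 in dhh1Δ (-0.086), DHH1 and HIS3 in nam7Δ (-0.452, -0.444), DEF1, SNF5 and HIS3 in rad51Δ (-0.194, -0.241, -0.136), SNF5 and SNF6 in snf2Δ (-0.134, -0.084), and MED1 and SNF5 in snf6Δ (-0.014, -0.164). SNF6 in def1Δ turned with DESeq2 size factors (0.004), the DESeq2 Wald test (0.005) and only the 2 genotypes compared (0.013), as did HIS3 with the last (0.011). DHH1 in nam7Δ turned with no filter on low counts (-0.022). With each library left out the ranges in def1Δ were -0.009 to 0.095 for MED1, -0.015 to 0.085 for SNF2, -0.112 to 0.074 for SNF6 and -0.167 to 0.094 for HIS3. They were -0.152 to 0.04 for MED1 in dhh1Δ, -0.165 to 0.016 for HIS3 in med1Δ, -0.299 to 0.297, -0.406 to 0.15 and -0.206 to 0.276 for DHH1, SNF5 and HIS3 in nam7Δ, and -0.542 to 0.122 for MED1 in rad51Δ. In snf2Δ they were -0.276 to 0.116 for MED1, -0.017 to 0.155 for SNF5 and -0.114 to 0.32 for SNF6, in snf5Δ -0.358 to 0.117 for MED1, and in snf6Δ -0.095 to 0.005 for SNF2 and -0.123 to 0.251 for SNF5.

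A replicate block, which treats equal replicate numbers as shared, gave 3829 changed genes in def1Δ and 1219 in rad51Δ, within 1.5 times in every comparison, and turned HIS3 in med1Δ (0.011). Equal numbers gave no clear sign of pairing: after removing group means, libraries of equal number in a mutant and BY4741 correlated at -0.286 to 0.16. The libraries of a group of 2 mirror each other once its mean is removed, so these values cannot exclude pairing.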

Other observations

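The test of a missing end of chromosome III in BY4741 was chosen only after its result was seen, as were the genes named in this part except FIT3, SER3, RDS1, GIT1, AAD3 and ADH7. ACO1, aconitase, was higher in snf2Δ (0.87) and lower in snf5Δ (-0.76) and snf6Δ (-0.91) than in BY4741, and IDH1, isocitrate dehydrogenase, was 1.13 in snf2Δ and -0.60 in snf6Δ. FIT3 was 2.74 in snf2Δ and -0.61 in snf5Δ. LYS9, of lysine synthesis, was -0.95 in snf2Δ and 0.72 in snf5Δ, and LEU4, of leucine synthesis, -0.43 and 0.64. SRG1, the noncoding transcript upstream of SER3, was 1.05 in snf2Δ and -1.28 in snf6Δ, the same direction as SER3 in each. SER3 overlaps SRG1 and can share reads with it, so the like directions are not separate results.

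Of the alpha-cell markers, SAG1, alpha-agglutinin, had 17 to 150 counts per library, MF(ALPHA)2 4 to 33 and STE3, the a-factor receptor, 0 to 18. Within genotypes the correlation of libraries was lowest in nam7Δ, at 0.9317. The first principal component held 45.5% of the variance, and the 3 BY4741 libraries lay at -40.28, -40.63 and -41.28 on it, between the 2 nam7Δ libraries at -47.74 and -28.22.

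Genes at the right end of chromosome III were near 0 in BY4741 and present in the mutants. RDS1 had 0 counts in BY4741 and 854 over the mutants, GIT1 0 and 204, AAD3 2 and 536, and ADH7 2 and 282, while CDC39 further inside had 1150 and 6393. A loss of this end from the BY4741 stock predicted 3 or fewer counts for each feature, and the highest was 7 (EMA35, against 360), which is above that bound and below the 20 set against it, so the explanation remains open and cannot be told apart from silencing of the end.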
